A study of Mus musculus and Homo sapiens with 74 samples.

How the data were processed

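Gene expression was measured in 74 samples, 38 livers of C57BL/6 mice and 36 wells of human primary hepatic stellate cells. The livers came from 4 groups: 8 mice on normal diet (chow) and 3 groups of 10 mice on FFD, the fast food diet named in the labels, treated with vehicle, with 1 mpk or with 5 mpk of an ACC (acetyl-CoA carboxylase) inhibitor (ACCi). The labels give 28 days of treatment for the 3 FFD groups and none for chow, and write the dose unit as mpk without spelling it out. The stellate cells came from 3 donors, and each donor had 2 wells of each of 6 treatments, kept without serum for 48 h: DMSO, ACCi at 300 nM, a TGF inhibitor (TGFi) at 5 uM, TGF beta (TGFb) at 5 ng/ml, TGFb with ACCi, and TGFb with TGFi. The labels name neither inhibitor. Replicate numbers of mice are names and give no order.

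For the livers, per the labels, libraries were made with a stranded mRNA kit and the notes name CASAVA, STAR 2.4 and the genome build mm10, with no counting program or annotation. The deposited liver tables hold gene-level count values that are not plain read counts: every value is a multiple of 0.5, 45.2% of them are not whole numbers, and between 55 and 69 values per library are below 0. The authors must therefore have subtracted or divided something that the notes do not state, and a difference in that step between libraries would not be seen. Of 23740 gene names found in any library, 16517 were in all of them, and a missing name was read as 0. The 125 names with a value below 0 in any library were left out, and the other 23615 were rounded to whole numbers; the values left out came to at most 0.827% of a library's total. For the stellate cells, the deposited files hold raw counts per amplicon, 1 amplicon per gene, from an AmpliSeq human transcriptome panel, and the notes name the build hg19. Of 20812 amplicon rows, 20731 were used; those left out were 10 spike-ins and genes linked to sex, which were not looked at in human samples. The 28 symbols that a spreadsheet had turned into dates were kept under the amplicon's name. Mouse symbols were matched to GENCODE M21 on mm10 for coordinates (19619 matched); no human annotation was at hand, so human genes carry the amplicon's name only.

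Total counts ran from 4381565 to 6121357 per liver and from 7718247 to 23503953 per well. Levels are given as CPM, the usual counts per library total scaled with TMM factors, the mean with its SD between animals or between donors. Counts are reads without molecular identifiers, so a low level is limited by counting error on top of the spread between animals or donors.

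Each comparison was made with the quasi-likelihood test of edgeR 4.0.16, with TMM normalization, the filterByExpr filter by group, and Benjamini-Hochberg adjustment at 0.05. A gene past that threshold is called changed. The 38 livers entered 1 fit with 4 groups and no covariate (34 residual degrees of freedom, 12887 genes tested, common biological coefficient of variation 0.214). The 2 wells of each donor and treatment were summed, because the donor and not the well is the biological replicate, and the 18 sums entered 1 fit with treatment and donor as terms (10 residual degrees of freedom, 14074 genes tested, coefficient 0.211). The donor term pairs the treatments within each donor. Wells of the same number were checked for a shared batch: 13 of 45 correlations between same-numbered wells of a donor were over 0.1, with a median of -0.06, so the well number was not used as a block in the comparisons reported. With the well number as a replicate block, on unsummed wells, TGFb against DMSO gave 4998 genes called; that setting treats wells as replicates.

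Gene lists, 26 for mouse and 27 for human, covered lipid and energy metabolism, matrix, stress, clock and inflammatory genes, and markers of the cell types a liver or a culture could hold; 1 mouse list of other tissues had too few measured members to test. Lists were tested with camera in edgeR and limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list. Beside each list stand its members called over all genes tested and, where given, the count adjusted over the list alone. A list's test compares its genes with all other genes, so a list can pass with few members called.

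The comparisons, tests, lists and the rule for named genes were fixed before the data were examined, except the comparison of TGFb+TGFi with DMSO, which was added afterwards. The design had read the liver values as counts; the tests were kept as fixed once the steps of 0.5 were found, and limma-trend on the unrounded values was added as an alternative. Genes named for a comparison are 12 key genes per species; the 6 highest and 6 lowest log2 fold changes among called genes with at least 5 CPM in the higher group and the same direction in all 3 donors, or in mice with at least 80% of the first group's livers beyond the second group's mean; and up to 4 members with the smallest p of each list that passed its test or had 3 or more members called. That ranking leaves out predicted genes, pseudogenes and immune receptor segments. A few genes that the rule names, key genes among them, were left out of the text and of the named-gene results afterwards, and no others took their place; they still count among the genes called and in the gene lists.

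Alternatives were DESeq2 1.42.0, RLE size factors, no filter, only the 2 groups compared, each donor left out, the L code (L1 to L5, a code of unknown meaning carried by each liver library) as a term, libraries marked T left out, unsummed wells, and no donor term. Added after the data were seen were limma-trend, the clock score (the mean standardised level of Dbp, Tef, Per3, Ciart and Hlf less that of Arntl, Npas2 and Clock, divided by 2) as a term, leaving out each liver in turn, leaving out 8 livers that stand apart from their group, and leaving out 4 wells of stellate cells that lie out of place. A liver stands apart where its root mean square log2 distance from the group's median, over 8266 genes, exceeds 1.5 times the median of all livers (0.26), or where the mean of 5 muscle genes exceeds 10 CPM. No 2 libraries of a group were copies of one another: differences between livers were at least 2.88 times what sampling of reads gives. The tests were run on simulated data with added changes: in the liver design edgeR recovered 69.7% of 1.5-fold, 80.6% of 2-fold and 100% of 4-fold changes, and in the stellate cell design 14.9%, 49.3% and 93.9%. Of the genes called in the liver simulation, 2.7% with edgeR and 6.1% with DESeq2 were unchanged genes. In the stellate cell simulation these shares were 3.5% and 15.9%. Tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.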

Results

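RNA was measured in 38 mouse livers and in 36 wells of human primary hepatic stellate cells, the cells of the liver that lay down matrix when activated. The inhibitor of ACC, the enzyme that makes malonyl-CoA for fatty acid synthesis, is called ACCi here. The livers fell into 4 groups: chow (n = 8), fast food diet (FFD) with vehicle (n = 10), FFD with ACCi at 1 mpk (n = 10) and FFD with ACCi at 5 mpk (n = 10). The labels give 28 days of treatment for the 3 FFD groups and no time for chow. The stellate cells of 3 donors received DMSO, ACCi at 300 nM, a TGF inhibitor (TGFi) at 5 uM, TGF beta (TGFb) at 5 ng/ml, TGFb with ACCi, or TGFb with TGFi, each in 2 wells per donor for 48 h. Total gene counts per liver ran from 4889526 to 6121357 with chow, from 4381565 to 5208018 with vehicle, from 4426019 to 5297233 with 1 mpk and from 4568549 to 5595763 with 5 mpk. Total amplicon counts per well ran from 8085377 to 10221440 with DMSO, 8657629 to 10892571 with ACCi, 8658607 to 23503953 with TGFi, 8239052 to 17674917 with TGFb, 9445775 to 15876239 with TGFb+ACCi and 7718247 to 10586063 with TGFb+TGFi. The 10 most abundant genes took between 14.7% and 27.9% of a liver's counts and between 9.7% and 17.2% of a well's. Each liver library carries a code from L1 to L5 whose meaning the labels do not give. Vehicle livers carry L1 and L2 only, chow livers L4 and L5 only, and 5 mpk livers L3, L4 and L5 only, so the diet comparison and the comparison of 5 mpk with vehicle have no code with both groups. Of the livers, 8 stood apart from their group: 2 with chow, 3 with 1 mpk, 3 with 5 mpk and 0 with vehicle. Of these, 1 mpk replicate 3 was marked for its muscle genes, with a distance from the group's median under the limit. Leaving out livers for their distance from the group narrows the spread by construction, so calls gained without them are partly built in.

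The comparison of FFD vehicle with chow asked what the diet does to the liver. Most matrix, macrophage and lipogenic genes were higher with FFD, and most genes of cholesterol synthesis, hepatocyte function and mitochondrial respiration were lower, but none of these lists passed with an estimated correlation (smallest adjusted p = 0.125). Ephb2, an ephrin receptor tyrosine kinase (mm10 chromosome 4:136647539-136835988, minus strand), stood at 39.2 ± 10.7 CPM (SD, n = 10) with vehicle and 0.516 ± 0.259 CPM (SD, n = 8) with chow, a 71.1-fold difference (log2 fold change 6.15 ± 0.39 SE, adjusted p = 3.55e-15). Col1a1, a chain of type I collagen (chromosome 11:94936224-94953042, plus strand), stood at 34.1 ± 11.3 CPM against 4.24 ± 4.2 CPM (7.78-fold, adjusted p = 1.37e-06). Timp1, an inhibitor of matrix proteases (chromosome X:20870166-20874735, plus strand), rose 13.1-fold (adjusted p = 7.98e-08), and Acta2, the smooth muscle actin of activated stellate cells, rose 3.44-fold (adjusted p = 0.00447). Among the genes of ACC itself, Acaca (chromosome 11:84129672-84401651, plus strand), which encodes the cytosolic enzyme, rose 2.86-fold to 199 ± 44.7 CPM (adjusted p = 8.45e-08), and Acacb (chromosome 5:114146535-114250761, plus strand), which encodes the mitochondrial form, rose 3.11-fold (adjusted p = 8.28e-05). Scd1, a fatty acid desaturase (chromosome 19:44394455-44407879, minus strand), rose 6.97-fold from 355 ± 192 CPM with chow (log2 fold change 2.8 ± 0.35 SE, adjusted p = 2.99e-08). Fasn, fatty acid synthase (chromosome 11:120805846-120824547, minus strand), rose 4.2-fold (adjusted p = 8.3e-05), and Srebf1, the transcription factor that drives lipogenesis (chromosome 11:60199089-60222581, minus strand), rose 1.86-fold (adjusted p = 0.000642). Tgfb1 rose 2.18-fold. Gpam (adjusted p = 0.0641) and Cpt1a (adjusted p = 0.299) were not called.

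In all, 6649 of 12887 genes were called, 3339 higher and 3310 lower with FFD, of which 1326 and 516 differed at least 2-fold. After Ephb2, the largest rises were those of Gpnmb (67.6-fold), Mmp12 (40.7-fold), Ly6d (33.5-fold), Lpl (16.2-fold) and Trem2 (16.2-fold), several of them genes of lipid-laden macrophages. The largest falls were those of Hsd3b5 (31.8-fold), Acot3 (22.2-fold), Gpx6 (18.5-fold), Ciart (17-fold), Mup7 (16.1-fold) and Serpina1e (15.8-fold). The vehicle mean of Mup7 was 155 CPM with all livers and 46 CPM without 1 of them. Acot3, Mup7 and Serpina1e have close paralogs, and the files do not show which of them a read came from. Collagen and matrix genes had 26 of 30 measured members higher (list adjusted p = 1.39e-13), Col3a1 at 135 CPM against 21.7 CPM, and macrophage markers 18 of 20 (adjusted p = 8.5e-14), with Itgax, Lgals3 and Cd9 among them. Chemokine and inflammatory signalling genes had 11 of 12 higher (adjusted p = 2.03e-05) and stellate cell markers 13 of 17 (adjusted p = 0.000149). Endothelial markers had 10 of 12 higher (11 adjusted over the list alone, adjusted p = 0.00156) and cell cycle genes 9 of 11 (adjusted p = 0.00111). Cholangiocyte markers had 4 of 6 higher (5 adjusted over the list alone, adjusted p = 0.0129). Neutrophil markers had 3 of 4 higher (4 adjusted over the list alone, adjusted p = 0.0396). Lipogenic genes had 12 members higher and 3 lower (adjusted p = 0.0129), glycolytic genes 10 and 3 (adjusted p = 0.0302), and genes of the NRF2 oxidative stress response 7 and 1 (adjusted p = 0.0129). Cholesterol synthesis genes had 20 of 23 lower and 0 higher (adjusted p = 1.39e-13); Sqle, the squalene oxidase, stood at 9.98 CPM with vehicle and 91.3 CPM with chow. Fatty acid oxidation genes had 17 of 24 lower and 1 higher (adjusted p = 0.0129), oxidative phosphorylation genes 16 of 27 lower (adjusted p = 0.00424) and hepatocyte markers 11 of 17 lower (adjusted p = 0.00111), Alb at 40100 CPM against 83300 CPM. Xenobiotic metabolism genes had 8 lower and 2 higher (adjusted p = 0.0232) and circadian clock genes 7 lower and 2 higher (adjusted p = 0.0129), with Per3 and Tef lower and Arntl higher. In the estimated correlation test none of these 17 lists passed (smallest adjusted p = 0.125). With the L code as a term 2230 genes were called, 2172 of them shared, and Orm2 changed direction. In that fit Acta2 (adjusted p = 0.111), Acacb (adjusted p = 0.194) and Fasn (adjusted p = 0.0685) were not called. Their log2 fold changes were 2.33, 1.51 and 2.84, against 1.78, 1.64 and 2.07 without the term. Acta2 was not called with the clock score as a term either (log2 fold change 0.93, adjusted p = 0.377). Without the livers standing apart Gpam (adjusted p = 0.0236) and Cpt1a (adjusted p = 0.00128) were called. These gains are partly built in by the choice of livers.

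ACCi at 1 mpk was compared with vehicle to ask what the lower dose does in mice on the same diet. Of the clock genes 7 of 15 were higher, of the NRF2 genes 4 of 12 were lower, and neither the lipogenic genes nor Col1a1 were called. Per3, a repressor of the clock (chromosome 4:151003652-151044665, minus strand), stood at 60 ± 22.2 CPM (SD, n = 10) against 15.1 ± 6.96 CPM with vehicle (SD, n = 10), a 3.97-fold difference (log2 fold change 1.99 ± 0.24 SE, adjusted p = 1.18e-06). Ephb2 stood at 9.47 ± 4.72 CPM, 4.08-fold lower than with vehicle (adjusted p = 4.05e-07). Dbp, a clock-driven transcription factor, rose 4.38-fold to 117 ± 58.4 CPM (adjusted p = 0.000341), and Ly6d, a surface marker, fell 5.41-fold to 5.45 ± 3.07 CPM (adjusted p = 4.08e-05). Timp1 fell 2.11-fold (adjusted p = 0.0359), a call lost when any 1 of 10 livers was left out. Col1a1 was at 26.6 ± 20.5 CPM (adjusted p = 0.699), Acaca at a log2 fold change of -0.04 (adjusted p = 0.942), Srebf1 at 0.48 (adjusted p = 0.2) and Fasn at -0.34 (adjusted p = 0.728), none of them called. Without the livers standing apart Srebf1 was called (log2 fold change 0.62, adjusted p = 0.00982). That gain is partly built in by the choice of livers.

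Of the genes tested at 1 mpk, 456 were called, 223 higher and 233 lower, with 48 and 46 differing at least 2-fold. Without the livers standing apart 1800 were called, and with only the 2 groups compared 853. The rise to 1800 is partly built in by the choice of livers. Other large rises were those of Acot3 (7.77-fold), Ciart (4.99-fold), Onecut1 (4.03-fold) and Pygm (3.64-fold), and other large falls those of Zbtb16 (4.08-fold), Adam22 (4.07-fold), Pitx3 (3.89-fold) and Cyp26b1 (3.57-fold). Pygm is a muscle enzyme and its call rested on 1 liver, without which its log2 fold change was 0.61 (adjusted p = 0.0863); the call of Pitx3 was lost without any 1 of 11 livers and that of Cyp26b1 without 1. The mean of Pitx3 at 1 mpk was 1.7 CPM with all livers and 0.709 CPM without 1 other liver. Clock genes had 7 of 15 members higher and 2 lower (3 lower adjusted over the list alone; list adjusted p = 0.000625), Tef among them. NRF2 genes had 4 of 12 lower (6 adjusted over the list alone; adjusted p = 1.11e-05), including Gsta1, Gstm3, Gstm1 and Gclc. Those were the only lists of 10 that also passed with an estimated correlation (adjusted p = 0.034 for both). Macrophage markers had 1 of 20 lower (3 adjusted over the list alone; adjusted p = 0.000704, adjusted p = 0.517 with an estimated correlation), with Cd9 called. Chemokine and inflammatory signalling genes had 1 of 12 lower (6 adjusted over the list alone, adjusted p = 0.0123). Red cell genes had 3 of 4 higher (adjusted p = 0.0123), among them Hbb-bs and Hbb-bt, close paralogs. Bile acid genes had 3 of 17 higher (Cyp7a1, Slc10a1 and Nr1h4) but did not pass as a list (adjusted p = 0.596), with a median log2 fold change of -0.07 and a mean of 0.11. Glycerolipid genes had 1 member higher, Lipe, and 3 lower, Lpin1, Lpin2 and Plin3 (list adjusted p = 0.0522). Lipogenic genes had 0 of 20 called (adjusted p = 0.903) and collagen and matrix genes 1 lower (adjusted p = 0.0802). Within code L2, which holds 6 livers at 1 mpk and 2 with vehicle, 1 gene was called and 774 had an unadjusted p below 0.05. Of the 448 genes called at 1 mpk that could be tested there, 446 had the same direction. Those livers were among the ones that gave the calls, so the shared direction is largely built in and is no independent check. With the L code as a term 2 genes were called, and with the clock score as a term 2395, 176 of them shared, with Dbp at a log2 fold change of -0.02.

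ACCi at 5 mpk was compared with vehicle to ask what the higher dose does. Ephb2 and 16 of 30 collagen and matrix genes were lower, and Srebf1, 12 of 23 cholesterol synthesis genes, 5 of 20 lipogenic genes and 7 of 15 clock genes were higher, but no list passed with an estimated correlation. Srebf1 stood at 607 ± 150 CPM (SD, n = 10) against 321 ± 40.2 CPM with vehicle (SD, n = 10), a 1.89-fold difference (log2 fold change 0.92 ± 0.2 SE, adjusted p = 0.00109). Col1a1 stood at 15.1 ± 7.89 CPM, 2.24-fold lower than with vehicle (log2 fold change -1.16 ± 0.36 SE, adjusted p = 0.0227). Ephb2 fell 12.6-fold to 3.07 ± 1.8 CPM (adjusted p = 1.4e-12). Per3 rose 6.11-fold to 92.6 ± 26.4 CPM (adjusted p = 1.19e-09), and Arntl, the activator it opposes, fell 5.2-fold to 6.3 ± 3.94 CPM (adjusted p = 7.53e-07). Pnpla3, a lipid droplet lipase (chromosome 15:84167837-84187236, plus strand), stood at 37.3 CPM against 7.37 CPM (adjusted p = 1.62e-06). Timp1 fell 1.94-fold (adjusted p = 0.0239), a call lost without 1 vehicle liver (adjusted p = 0.0522). Acaca (adjusted p = 0.474), Acacb (adjusted p = 0.464), Fasn (adjusted p = 0.245), Scd1 (adjusted p = 0.796), Gpam (adjusted p = 0.103), Acta2 (adjusted p = 0.209), Cpt1a and Tgfb1 were not called. Without the livers standing apart Fasn (log2 fold change 0.87, adjusted p = 0.026), Gpam (adjusted p = 0.0372) and Acta2 (log2 fold change -0.91, adjusted p = 0.0111) were called, Acta2 also with only the 2 groups compared (adjusted p = 0.034). Calls gained by leaving out those livers are partly built in, since the livers were chosen for lying far from their group.

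At 5 mpk 2265 genes were called, 1132 higher and 1133 lower, with 132 and 131 differing at least 2-fold. The largest rises were those of Acot3 (21.2-fold), Ciart (8.73-fold), Sult2a7 (7.58-fold, with close paralogs), Pnpla5 (7.34-fold) and Hamp2 (6.86-fold), and the largest falls, beside Ephb2, those of Pitx3 (13.1-fold), Zbtb16 (7.65-fold), Npas2 (5.72-fold) and Ly6d (5.12-fold). Cholesterol synthesis genes had 12 of 23 higher (16 adjusted over the list alone; list adjusted p = 2.53e-08), Stard4 and Fdft1 among them. Lipogenic genes had 5 of 20 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.00618), with Thrsp and Elovl6 called. Collagen and matrix genes had 16 of 30 lower (21 adjusted over the list alone; adjusted p = 1.7e-06), Col3a1 at 57.2 CPM against 135 CPM (adjusted p = 0.000257) and Fbn1 and Dpt also lower. Stellate cell markers had 3 of 17 lower (adjusted p = 0.00666) and endothelial markers 4 of 12 (5 adjusted over the list alone, adjusted p = 0.00618). Cell cycle genes had 5 of 11 lower (7 adjusted over the list alone, adjusted p = 0.000779). Chemokine and inflammatory signalling genes had 3 of 12 lower (5 adjusted over the list alone, adjusted p = 0.0371). Macrophage markers had 1 of 20 lower (adjusted p = 0.0082). Hepatocyte markers had 7 of 17 higher (8 adjusted over the list alone; adjusted p = 0.00105), with Alb, Ttr and Apoa1 among them, xenobiotic genes 7 of 13 (8 adjusted over the list alone; adjusted p = 0.000391), with Por, Ces2a and Cyp2b9, and oxidative phosphorylation genes 4 of 27 (0 adjusted over the list alone; adjusted p = 0.0445). NRF2 genes had 6 of 12 lower and 2 higher (adjusted p = 0.000748) and clock genes 7 of 15 higher and 2 lower (adjusted p = 0.000748). None of these 13 lists passed with an estimated correlation; the smallest values were adjusted p = 0.0678 for clock genes and adjusted p = 0.0943 for xenobiotic genes. Glycerolipid genes had 3 higher and 6 lower (6 and 9 adjusted over the list alone; adjusted p = 0.141), ER stress genes 1 higher and 4 lower (adjusted p = 0.119), Gdf15 and Trib3 among the lower, and bile acid genes 4 higher and 2 lower (adjusted p = 0.978; median log2 fold change -0.26, mean 0). With the L code as a term 80 genes were called, 78 of them shared, and with the clock score as a term 4283, 1108 of them shared. With the clock score Srebf1 went from a log2 fold change of 0.92 to 0.11 (adjusted p = 0.776) and was not called. Timp1 lost its call but stayed at -0.88, against -0.96 (adjusted p = 0.174). Pitx3 went from -3.71 to -1.62 (adjusted p = 0.149) and Npas2, part of the score, from -2.52 to -0.6 (adjusted p = 0.14), both losing their calls. Col1a1 (adjusted p = 0.00348) and Ephb2 (adjusted p = 5.56e-09) were called. Col1a1, at -1.16 in the main fit, lost its call in limma-trend (log2 fold change -1.29, adjusted p = 0.0772) and with the L code (-1.88, adjusted p = 0.303). Srebf1 lost its call with the L code, going from 0.92 to 0.54 (adjusted p = 0.693).

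The 2 doses were compared with each other to ask what changes between them. Saa1, Saa2, Pnpla3 and Pnpla5 were among the genes higher at 5 mpk, and Ephb2 was among those lower. Pnpla3 stood at 37.3 ± 25.8 CPM with 5 mpk (SD, n = 10) and 7.97 ± 2.68 CPM with 1 mpk (SD, n = 10), a 4.65-fold difference (log2 fold change 2.22 ± 0.32 SE, adjusted p = 0.000298). Saa2, an acute phase protein gene with a close paralog, stood at 1330 ± 1860 CPM against 106 ± 110 CPM (12.6-fold, adjusted p = 0.0136), with an SD larger than the mean in both groups. Saa2 lost its call in limma-trend (log2 fold change 2.33, against 3.65 in edgeR; adjusted p = 0.142), with only the 2 groups compared (adjusted p = 0.0822) and with the L code as a term (adjusted p = 0.07), and Saa1 lost it in these 3 settings and without the libraries marked T. Ephb2 stood at 3.07 ± 1.8 CPM against 9.47 ± 4.72 CPM (3.08-fold lower, adjusted p = 0.00236). Gpam, the enzyme that begins glycerolipid synthesis, rose 1.69-fold to 888 ± 386 CPM (adjusted p = 0.0449). Srebf1 (adjusted p = 0.337), Fasn (adjusted p = 0.23), Col1a1 (adjusted p = 0.337), Acta2 (adjusted p = 0.0507) and Timp1 were not called. In all 95 genes were called, 52 higher and 43 lower at 5 mpk, with 18 and 8 differing at least 2-fold. That count ran from 39 to 189 with each liver left out in turn, and was 20 with only the 2 groups compared, 24 without the libraries marked T and 344 without the livers standing apart. The rise to 344 is partly built in by the choice of livers. Saa1 (7.57-fold), Pnpla5 (4.53-fold), Hamp2 (3.76-fold) and Sult2a7 (2.56-fold) were among the higher, and Pygm (3.55-fold), Gdf15 (2.76-fold), Myh11 (2.66-fold), Cyr61 (2.04-fold) and Fhl1 (1.76-fold) among the lower. Several calls were lost without any 1 of several livers: Pygm (27 livers), Fhl1 (25), Gpam (17), Gdf15 (9), Saa1 (8) and Myh11 (5). Without 1 liver at 1 mpk the log2 fold change of Pygm went from -1.83 to -0.56, and without another that of Gdf15 from -1.46 to -0.85. Without the livers standing apart Myh11 went from -1.41 to -0.66 (adjusted p = 0.137) and Fhl1 from -0.82 to -0.33 (adjusted p = 0.292). Cholesterol synthesis genes had 4 of 23 higher (16 adjusted over the list alone; list adjusted p = 3.06e-19, adjusted p = 0.0747 with an estimated correlation), with Mvd and Sc4mol called. Lipogenic genes had 2 higher (6 adjusted over the list alone; adjusted p = 1.81e-06, adjusted p = 0.253 with an estimated correlation) and acute phase genes 2 (10 adjusted over the list alone; adjusted p = 1.08e-09, adjusted p = 0.134 with an estimated correlation). Collagen and matrix genes had 1 lower (19 lower and 1 higher adjusted over the list alone; adjusted p = 1.57e-09), stellate cell markers 2 (9 adjusted over the list alone; adjusted p = 2.44e-08) and endothelial markers 0 (6 adjusted over the list alone; adjusted p = 1.48e-07). Of the 10 lists that passed, only the xenobiotic genes, with 0 called and 2 higher adjusted over the list alone (adjusted p = 5.49e-06), also passed with an estimated correlation (adjusted p = 0.0494). Clock genes did not pass (adjusted p = 0.185). Within code L3, with 6 livers at 5 mpk and 2 at 1 mpk, 0 genes were called and 95 of the 95 genes had the same direction. Within code L5, with 3 and 2, 0 were called and 94 of 94 had the same direction. These livers also gave the 95 calls, so the shared direction is largely built in and is no independent check.

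Whether ACCi moved genes against the diet was asked by counting genes called in opposite directions in the comparison of diet and the comparison of dose with vehicle. Ephb2, Timp1, Ly6d and Gsta1 rose with the diet and fell at both doses, Col1a1 and Col3a1 rose with the diet and fell at 5 mpk, and Per3, Ciart, Acot3 and Tef fell with the diet and rose at both doses. At 1 mpk 399 of 456 called genes had the opposite direction and 2 the same; 117.6 would be expected for independent lists. At 5 mpk 1857 of 2265 had the opposite direction and 23 the same, with 584.3 expected. Both comparisons share the vehicle livers, which by itself pushes log2 fold changes apart. With the vehicle livers split so that each comparison had its own, 118 genes were opposite at 1 mpk against 29.8 for independent lists. At 5 mpk 678 were opposite against 194.4. Vehicle livers carry codes L1 and L2, and chow and 5 mpk livers carry neither. A shift particular to the vehicle livers, by code or by clock, would therefore stay in both comparisons after the split. The excess cannot separate a reversal of the diet change from such a shift. With the L code as a term, 2 genes were called at 1 mpk and 80 at 5 mpk. Srebf1 and Pnpla3 did not follow the pattern of opposite directions: Srebf1 rose with the diet and rose again at 5 mpk. The mean clock score of the livers was 0.78 ± 0.36 with chow (SD, n = 8), -1.11 ± 0.37 with vehicle (SD, n = 10), 0.09 ± 0.74 with 1 mpk (SD, n = 10) and 0.4 ± 0.36 with 5 mpk (SD, n = 10).

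**Figure D1:**
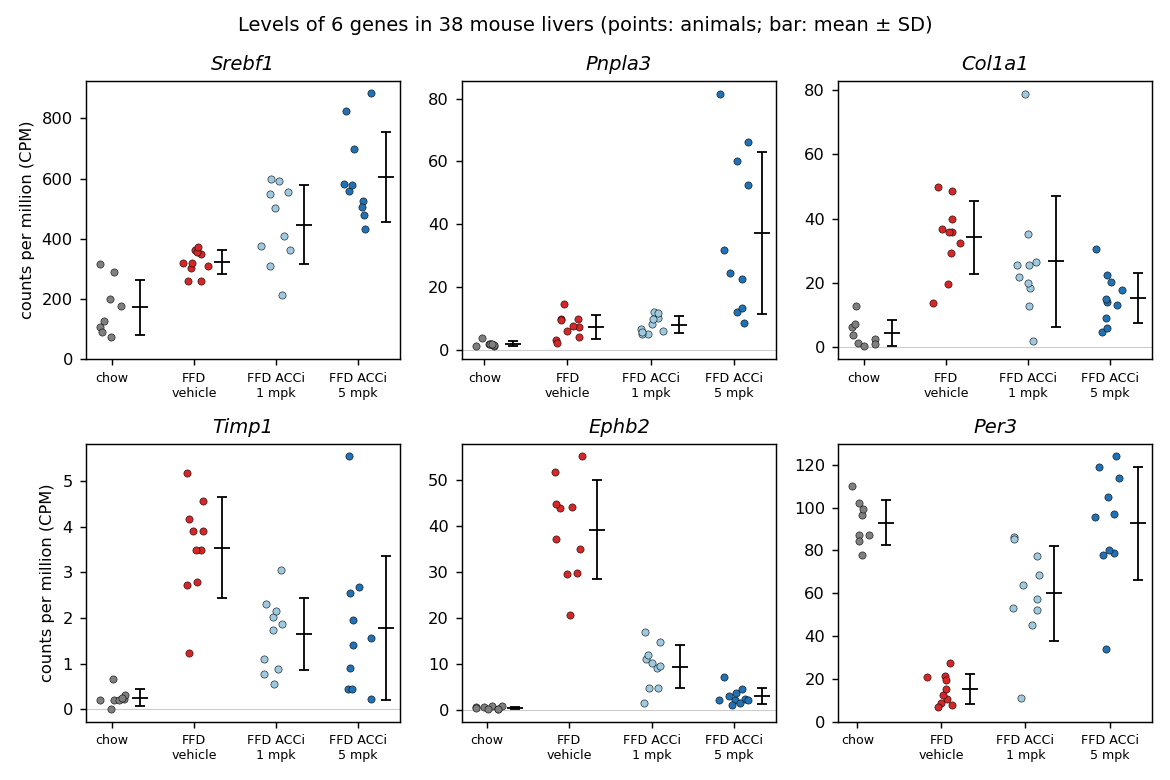
Level of 6 genes in each liver, in CPM, for chow, FFD vehicle, FFD with ACCi at 1 mpk and at 5 mpk; points are animals and bars the mean ± SD. Ephb2 averaged 0.516 CPM with chow, 39.2 CPM with vehicle, 9.47 CPM at 1 mpk and 3.07 CPM at 5 mpk.

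**Figure D2:**
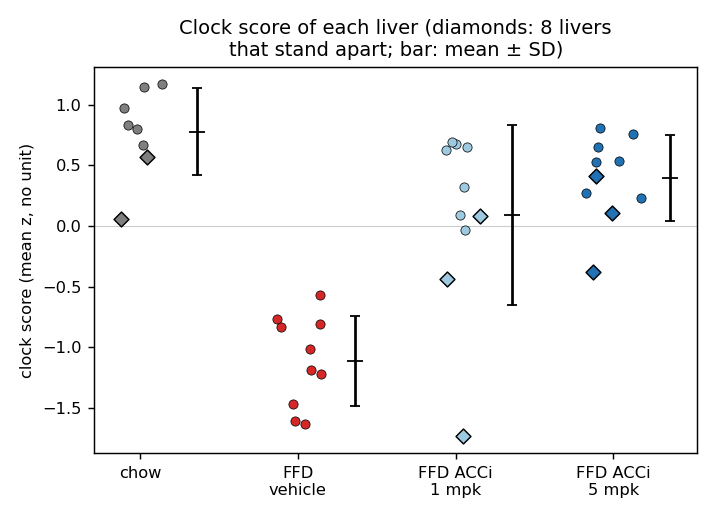
Clock score of each liver by group, without unit; points are animals, diamonds the 8 livers that stood apart from their group, and bars the mean ± SD. The mean was -1.11 with vehicle and 0.78 with chow.

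In the stellate cells, TGFb was compared with DMSO to ask what the cytokine that activates them changes. Of the TGFb targets 18 of 25 were higher and of the quiescent cell markers 7 of 14 were lower. Of 21 collagens 10 were higher, of 22 contractile genes 11 were higher, and of 22 chemokine and inflammatory genes 10 were lower. Those 3 lists did not pass with an estimated correlation (adjusted p = 0.138, 0.167 and 0.248). COL1A1 (amplicon AMPL3595460), the type I collagen chain, stood at 44600 ± 1150 CPM with TGFb and 18600 ± 3920 CPM with DMSO (SD, n = 3 donors), a 2.44-fold difference (log2 fold change 1.29 ± 0.17 SE, adjusted p = 0.000257). ACTA2 (AMPL10957017), the actin of myofibroblasts, stood at 2870 ± 2030 CPM against 659 ± 635 CPM (SD, n = 3 donors; 5.05-fold, adjusted p = 0.000464). TAGLN (AMPL10759047), an actin-binding protein gene, rose 5.28-fold (adjusted p = 0.000204). CTGF (AMPL11335505), a matrix-associated growth factor, rose 7.49-fold (adjusted p = 0.00225). COL3A1 (AMPL4620938; adjusted p = 0.916), TIMP1 (AMPL8422310; adjusted p = 0.117), SREBF1 (AMPL53576; adjusted p = 0.392), SCD (AMPL27982622; adjusted p = 0.2), FASN (AMPL30034450), ACACA (AMPL22279197) and ACACB were not called. In all 2713 of 14074 genes were called, 1309 higher and 1404 lower with TGFb, with 491 and 808 differing at least 2-fold. That count was between 828 and 1762 with a donor left out and 1373 with only the 2 treatments compared. The largest rises were those of COMP (278-fold, from 0.429 ± 0.307 to 131 ± 80.4 CPM), CLEC18B (247-fold, with close paralogs), COL10A1 (130-fold), TSPAN2 (72.8-fold), IL11 (40-fold) and ANKRD1 (38.5-fold). The largest falls were those of ADH1B (log2 fold change -6.76), PPP1R1B (log2 fold change -6.75), EVI2B (66.6-fold), COLEC12 (45.1-fold), GDF5 (30-fold) and KBTBD10 (25.3-fold). KBTBD10 lost its call with any donor left out, with a log2 fold change of -1.54 in place of -4.66 without 1 of them, as well as in DESeq2 (-2.87, adjusted p = 0.0646) and with only the 2 treatments compared (adjusted p = 0.0677). PPP1R1B lost its call in DESeq2 (log2 fold change -3.06, adjusted p = 0.0954). TGFb target genes had 18 of 25 higher and 2 lower (21 and 3 adjusted over the list alone; list adjusted p = 3.35e-15), with PMEPA1 and TGFBI among them. Matrix glycoprotein and crosslinking genes had 16 of 30 higher and 1 lower (21 and 3 adjusted over the list alone; adjusted p = 1.41e-09), with FN1, BGN and SPARC, collagens 10 of 21 higher and 3 lower (11 and 3 adjusted over the list alone; adjusted p = 1.89e-05), and contractile genes 11 of 22 higher and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 8.69e-07). Quiescent cell markers had 7 of 14 lower and 1 higher (adjusted p = 4.31e-06), with PLIN2, PPARG, HGF and CYGB lower. Chemokine and inflammatory genes had 10 of 22 lower (adjusted p = 1.96e-06), with CXCL6 and SOD2. Interferon genes had 7 of 17 lower (adjusted p = 0.00195). Growth factor genes had 9 of 19 higher and 3 lower (adjusted p = 0.00301), epithelial genes 3 of 7 higher (adjusted p = 0.00335), with KRT7 and KRT18, serine and amino acid synthesis genes 3 of 19 higher (adjusted p = 0.0212), and glycerolipid genes 2 higher and 5 lower (adjusted p = 0.0368), with a median log2 fold change of 0.02 and a mean of -0.83. Of these 11 lists, 3 also passed with an estimated correlation, the TGFb targets (adjusted p = 0.0232), matrix genes (adjusted p = 0.00164) and quiescent cell markers (adjusted p = 0.0273).

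ACCi alone and TGFi alone were each compared with DMSO to ask what either inhibitor does without added TGFb. No gene was called with ACCi: edgeR called 0 (smallest adjusted p = 0.825), 801 genes had an unadjusted p below 0.05, and DESeq2 called 3. COL1A1 stood at 11200 ± 1540 CPM with ACCi against 18600 ± 3920 CPM (SD, n = 3 donors; log2 fold change -0.73 ± 0.17 SE) and ACTA2 at 287 ± 276 CPM against 659 ± 635 CPM, neither called. FASN and SREBF1 had log2 fold changes of 0.99 and 0.83, not called. As lists, the contractile genes were lower (0 called, 6 lower adjusted over the list alone; list adjusted p = 1.17e-15), as were the collagens (2 lower adjusted over the list alone; adjusted p = 5.48e-07), and lipogenic genes were higher (1 higher adjusted over the list alone; adjusted p = 2.76e-06). Matrix genes were lower (adjusted p = 9.55e-06) and were the only list of 13 to pass with an estimated correlation (adjusted p = 0.0278). With TGFi edgeR called 0 genes (smallest adjusted p = 0.735), 317 had an unadjusted p below 0.05, and DESeq2 called 2. COL1A1 and ACTA2 had log2 fold changes of -0.55 and -1.14, not called. Of 10 lists that passed with TGFi, 3 passed with an estimated correlation: matrix genes (adjusted p = 0.000568; 2 lower adjusted over the list alone), contractile genes (adjusted p = 0.0476) and cholesterol synthesis genes (adjusted p = 0.0476; 3 higher adjusted over the list alone). Of the 12 wells with ACCi or TGFi alone, 4, all of 1 donor, lay on the other inhibitor's side of a score of the TGFb+ACCi response. Without them 33 genes were called with ACCi, 26 higher and 7 lower. FASN (log2 fold change 1.28) and SREBF1 (1.11) were among the higher (adjusted p = 0.0221 for both). The ACCi wells left out were those scoring low for the ACCi response, so a larger ACCi effect without them is partly built in.

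TGFb+ACCi was compared with TGFb to ask whether ACC inhibition changes activated stellate cells. Of the contractile genes 10 of 22 were lower, and 1 of 25 TGFb targets was called. NRF2 genes (2 of 15 higher) and lipogenic genes (1 of 18) passed as lists with the preset correlation but not with an estimated one (adjusted p = 0.266 for both). ACTA2 stood at 452 ± 334 CPM with TGFb+ACCi against 2870 ± 2030 CPM with TGFb (SD, n = 3 donors), 6.52-fold lower (log2 fold change -2.71 ± 0.35 SE, adjusted p = 0.0111). TAGLN stood at 1500 ± 966 CPM against 4710 ± 2810 CPM (SD, n = 3 donors; 3.24-fold lower, adjusted p = 0.0211). COL1A1 stood at 26200 ± 2980 CPM against 44600 ± 1150 CPM (SD, n = 3 donors; 1.71-fold lower, adjusted p = 0.045). COL1A1 and TAGLN lost their calls with any 1 donor left out, ACTA2 with 1 of the 3 donors left out (adjusted p = 0.402), and all 3 without the donor term. CTGF (adjusted p = 0.685), TIMP1 (adjusted p = 0.921), COL3A1 (adjusted p = 0.166), SREBF1 (log2 fold change 1.54, adjusted p = 0.0612), FASN (adjusted p = 0.11), SCD (adjusted p = 0.196), ACACA (adjusted p = 0.166) and ACACB were not called in edgeR. DESeq2 called SREBF1 (adjusted p = 0.00283) and FASN (adjusted p = 0.0309), and edgeR with only the 2 treatments compared called SREBF1, FASN, SCD and ACACA. In the simulation of this comparison 15.9% of the genes that DESeq2 called were unchanged, against 3.5% with edgeR. In all 178 genes were called, 83 higher and 95 lower, with 53 and 51 differing at least 2-fold. The largest rises were those of PCDHAC2 (8.5-fold), ATF3, a stress-induced transcription factor (7.04-fold), TM6SF1 (6.34-fold), TSLP (6.2-fold), SAT1 (3.94-fold) and AKR1C1 (3.91-fold); PCDHAC2 and AKR1C1 have close paralogs. Among the largest falls, beside ACTA2, were those of MRVI1 (8.85-fold), CCL11 (8.67-fold), LMOD1 (8.32-fold) and WFDC1 (7.35-fold). All the rises and falls named here lost their calls without 1 of the donors, and CCL11 ran from a log2 fold change of -4.01 to -2.03 with a donor left out. Contractile genes had 10 of 22 lower (18 lower and 1 higher adjusted over the list alone; list adjusted p = 2.43e-21, adjusted p = 0.022 with an estimated correlation), with CALD1, TPM2 and CNN1. Matrix genes had 2 of 30 lower, FBLN5 and THBS1 (7 adjusted over the list alone; adjusted p = 1.4e-06, adjusted p = 0.0156 with an estimated correlation). The other 11 of 13 lists passed only with the preset correlation. Among these, NRF2 genes had 2 of 15 higher, HMOX1 and OSGIN1 (9 adjusted over the list alone; adjusted p = 5.1e-09), ER stress genes 1 of 18 (6 adjusted over the list alone; adjusted p = 5.1e-09), lipogenic genes 1 of 18, ELOVL6 (9 adjusted over the list alone; adjusted p = 0.000104), and cholesterol synthesis genes 1 of 23 (8 higher and 1 lower adjusted over the list alone; adjusted p = 4.75e-05). Cell cycle genes had 0 called (17 lower adjusted over the list alone; adjusted p = 3.88e-11), collagens 1 lower (5 adjusted over the list alone; adjusted p = 0.000805) and growth factors 2 lower (4 adjusted over the list alone; adjusted p = 0.00183), with IGFBP3. Serine and amino acid synthesis genes were higher as a list (adjusted p = 0.0025; median log2 fold change 0.8). TGFb targets did not pass (1 lower; adjusted p = 0.0596). The 178 calls fell to between 0 and 52 with a donor left out and to 0 without the donor term. They rose to 1152 without the 4 wells out of place and to 1022 in DESeq2. Without those wells SREBF1 (adjusted p = 0.000201), FASN (adjusted p = 0.00221), ACACA (adjusted p = 0.016) and SCD (adjusted p = 0.0203) were called, all higher. None of those wells is in this comparison, and the log2 fold change of SREBF1 went only from 1.54 to 1.56. They act through the shared fit, and leaving out wells for lying out of place can lower the spread it estimates. The calls gained without them are therefore no independent evidence.

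TGFb+TGFi was compared with TGFb to ask what blocking the TGFb signal undoes. Of the TGFb targets 19 of 25 were lower. With 11 of 21 collagens and 12 of 22 contractile genes lower and 7 of 14 quiescent cell markers higher, those 3 lists did not pass with an estimated correlation (adjusted p = 0.111, 0.135 and 0.054). COL1A1 stood at 17200 ± 3510 CPM against 44600 ± 1150 CPM with TGFb (SD, n = 3 donors), 2.63-fold lower (log2 fold change -1.4 ± 0.17 SE, adjusted p = 0.000135). ACTA2 fell 5.55-fold to 611 ± 684 CPM (SD, n = 3 donors; adjusted p = 0.000317) and TAGLN 4.53-fold to 1210 ± 1120 CPM (SD, n = 3 donors; adjusted p = 0.000343). CTGF fell 6.02-fold (adjusted p = 0.00425). TIMP1 (adjusted p = 0.102), SCD (adjusted p = 0.155), COL3A1, SREBF1 and FASN were not called. In all 2940 genes were called, 1509 higher and 1431 lower, with 872 and 530 differing at least 2-fold. That count was between about 7.1e2 (rounded) and 2112 with a donor left out and 1448 with only the 2 treatments compared. The largest rises were those of ADH1B (log2 fold change 6.75), PPP1R1B (77.4-fold), COLEC12 (43.6-fold), GDF5 (29.4-fold), CYP4X1 (25.9-fold) and GALNTL2 (21.8-fold), and the largest falls those of COL10A1 (235-fold), COMP (117-fold), IL11 (62.5-fold), TSPAN2 (45.4-fold), CLEC18B (42.3-fold) and ST6GAL2 (38-fold). In DESeq2 PPP1R1B was not called (log2 fold change 3.06, against 6.27 in edgeR; adjusted p = 0.09). TGFb targets had 19 of 25 lower and 2 higher (21 and 2 adjusted over the list alone; list adjusted p = 4.3e-15, adjusted p = 0.0327 with an estimated correlation), matrix genes 17 lower and 1 higher (adjusted p = 1.96e-11, adjusted p = 0.000849 with an estimated correlation), collagens 11 lower and 3 higher (adjusted p = 2.97e-06) and contractile genes 12 lower and 1 higher (adjusted p = 1.67e-07). Quiescent cell markers had 7 higher and 1 lower (adjusted p = 9.82e-05), with PLIN2, PPARG and HGF. Chemokine and inflammatory genes had 10 higher and 1 lower (adjusted p = 0.000334) and interferon genes 7 higher (adjusted p = 0.000176). Growth factors had 9 lower and 2 higher (adjusted p = 0.00236) and epithelial genes 3 lower (adjusted p = 0.00701). Of the 9 lists, only TGFb targets and matrix genes passed with an estimated correlation.

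**Figure D3:**
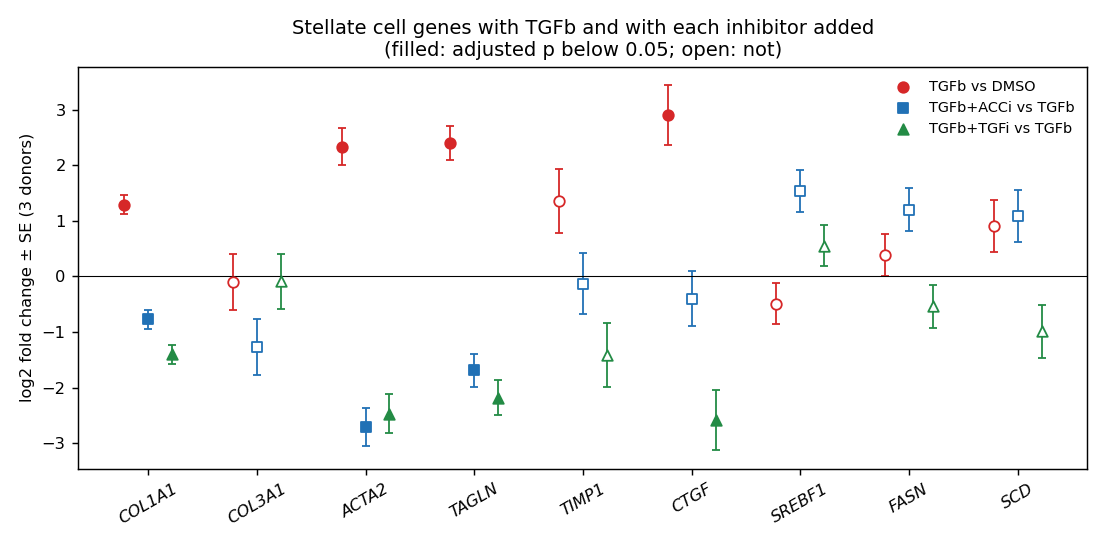
Log2 fold change ± SE of 9 genes in stellate cells of 3 donors for TGFb against DMSO (circles), TGFb+ACCi against TGFb (squares) and TGFb+TGFi against TGFb (triangles); filled symbols have an adjusted p below 0.05. ACTA2 stood at 2.34, -2.71 and -2.47, and CTGF at 2.91, -0.4 and -2.59.

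The interaction of each inhibitor with TGFb asked whether its effect differs between cells with and without TGFb. For ACCi edgeR called 0 genes (smallest adjusted p = 0.405), 747 had an unadjusted p below 0.05, and DESeq2 called 3; ACTA2 had a log2 difference of -1.57 (adjusted p = 0.923). Its contractile genes were lower as a list (2 lower adjusted over the list alone; list adjusted p = 1.06e-06) and its cell cycle genes also (adjusted p = 5.73e-07), but 0 of the 6 lists that passed did so with an estimated correlation. For TGFi 854 genes were called, 450 higher and 404 lower. COMP, a cartilage matrix protein gene, had a log2 difference of -7.72 ± 1.48 SE (adjusted p = 0.0108), and IL11, a profibrotic cytokine gene, one of -4.77 ± 0.75 SE (adjusted p = 0.00389). COL10A1, CHST6, KRT14 and NGEF were also among the lowest, and TAGLN had -1.51 ± 0.42 SE (adjusted p = 0.0498). EVI2B had the smallest adjusted p of the highest genes (log2 difference 5.78, adjusted p = 0.000205), beside PPP1R1B, ADH1B, COLEC12, GDF5 and GALNTL2; PPP1R1B was not called in DESeq2 (adjusted p = 0.328). With a donor left out, only EVI2B, ADH1B and CHST6 of the genes named so far for TGFi kept their calls each time. TAGLN and COLEC12 lost theirs with any donor left out, and TAGLN also with RLE size factors (adjusted p = 0.0561). Without 1 donor COLEC12 went from 5.36 to 3.93, and without another COL10A1 from -7.09 to -5.02. COL1A1 (adjusted p = 0.0518), CTGF (adjusted p = 0.0991) and ACTA2 (adjusted p = 0.112) were not called. Without the 4 wells out of place COMP (adjusted p = 0.0884), COL10A1 (adjusted p = 0.114) and NGEF (adjusted p = 0.0652) lost their calls, and COL1A1 (adjusted p = 0.0253) and ACTA2 (adjusted p = 0.0472) gained one. TGFb targets had 9 lower and 1 higher (16 and 2 adjusted over the list alone; adjusted p = 2.89e-10), matrix genes 5 lower (8 adjusted over the list alone; adjusted p = 4.23e-05, adjusted p = 0.0259 with an estimated correlation) and quiescent cell markers 4 higher (7 higher and 1 lower adjusted over the list alone; adjusted p = 4.24e-06, adjusted p = 0.0259 with an estimated correlation). Cholesterol synthesis genes had 3 lower (11 adjusted over the list alone; adjusted p = 2.23e-05) and lipogenic genes 3 lower (4 adjusted over the list alone; adjusted p = 0.00358). Of 13 lists that passed, 2 passed with an estimated correlation. With a donor left out between 43 and 349 genes were called for TGFi.

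TGFb+TGFi was also compared with DMSO, a comparison chosen after the data were seen, to ask whether cells given both differ from untreated cells. In edgeR 0 genes were called, 134 had an unadjusted p below 0.05, and DESeq2 called 0. COL1A1 had a log2 fold change of -0.11, ACTA2 -0.14 and CTGF 0.32, none called. Chemokine and inflammatory genes were the only list to pass (0 called, adjusted p = 0.00271, and adjusted p = 0.888 with an estimated correlation).

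Whether the inhibitors moved genes against TGFb was asked in the same way as for the diet. ACTA2, TAGLN and COL1A1 rose with TGFb and fell with either inhibitor, the calls of TAGLN and COL1A1 with ACCi being lost with any donor left out. CTGF rose with TGFb, fell with TGFi and was not called with ACCi (adjusted p = 0.685); the responses to the 2 inhibitors were not compared by a test. With ACCi 120 of 178 called genes had the opposite direction to their TGFb change and 1 the same, where 17.1 would be expected for independent lists. With TGFi 2302 of 2940 had the opposite direction and 0 the same, with 283.6 expected. Both comparisons share the TGFb wells. With those wells split by replicate number, 121 genes were opposite with ACCi against 22.2 for independent lists, and 2047 with TGFi against 262.6. The split wells still come from the same donors, so what a donor's TGFb wells have in common stays in both comparisons. The split therefore does not make the comparisons independent.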

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

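The tests of the clock genes, of the stellate cell wells and of the livers standing apart were chosen after the results they weigh were seen.

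A liver was singled out where Dixon's ratio, its gap to the nearest liver of its group divided by the group's range, exceeded its 95% critical value. For genes the ratio was taken on log2 CPM with a small count added, while the levels printed beside it are plain CPM. The summary measures were not transformed. Among 184 tests over 43 genes and 3 summary measures, 26 livers' values were singled out. Chance flags about 1 in 20 groups, so about 9 of them would come by chance, and most of the rest belong to a few livers.

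At 1 mpk, replicate 1 was far from the other 9 livers in 8 measures. It was lowest for Per3 (ratio 0.681; 11.2 CPM, others 45.2 to 86.2), Ciart (0.627; 0.294 CPM, others 4.35 to 14.6), Dbp (0.626; 10.3 CPM, others 65.1 to 193) and Col1a1 (0.498; 1.76 CPM, others 12.6 to 79). It was highest for Mup7 (0.555; 4110 CPM, others 27.5 to 257), Pitx3 (0.522; 10.6 CPM, others 0.17 to 1.94) and the distance from the group's median (0.588), and lowest for the clock score (0.536; -1.73, others -0.435 to 0.688). Replicate 3 was highest for Pygm (0.728; 46.2 CPM, others 1.76 to 4.59) and for the mean of 5 muscle genes (0.998; 127 CPM), and replicate 10 for Cyr61 (0.646; 14.8 CPM, others 3.1 to 5.48).

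At 5 mpk, replicate 2 was lowest for Acot3 (0.69; 1.53 CPM, others 15.6 to 41) and Per3 (0.641; 34.2 CPM, others 78.1 to 124) and highest for Adam22 (0.533; 12.2 CPM, others 0.682 to 3) and Cyp26b1 (0.468; 20.1 CPM, others 0.392 to 4.07). Replicate 8 was lowest for Acaca (0.555; 78.2 CPM, others 177 to 341). With vehicle, replicate 6 was lowest for Gpnmb (0.685; 6.96 CPM, others 34.9 to 72.1), Lpl (0.663; 24.6 CPM, others 54.8 to 82.1), Mmp12 (0.547; 7.98 CPM, others 21.5 to 47.9), Timp1 (0.529; 1.23 CPM, others 2.72 to 5.19) and Scd1 (0.473; 1210 CPM, others 2070 to 3770), and highest for Mup7 (0.489; 1140 CPM, others 7.6 to 100) and the distance from the group's median (0.508). With chow, replicate 7 was lowest for Myh11 (0.658; 0 CPM, others 1.41 to 3.59) and highest for Pnpla3 (0.542; 3.74 CPM, others 1.09 to 1.98), and replicate 6 was the only liver with counts of Pnpla5 (ratio 1; 0.207 CPM, others 0).

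The responses to the doses differed by test in 95 genes. The named ones, as log2 differences of 5 mpk from 1 mpk, were Saa2 (3.65), Saa1 (2.92), Pnpla3 (2.22), Pnpla5 (2.18), Hamp2 (1.91), Sult2a7 (1.35), Gpam (0.75), Fhl1 (-0.82), Cyr61 (-1.03), Myh11 (-1.41), Gdf15 (-1.46), Ephb2 (-1.62) and Pygm (-1.83). The response of stellate cells to TGFi differed with TGFb in 854 genes. The named ones were PPP1R1B (6.32), ADH1B (6.13), EVI2B (5.78), COLEC12 (5.36), GDF5 (5.05), GALNTL2 (4.67), TAGLN (-1.51), IL11 (-4.77), NGEF (-4.77), KRT14 (-5.03), CHST6 (-5.13), COL10A1 (-7.09, and -5.02 without 1 donor) and COMP (-7.72), as log2 differences.

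Clock genes differed between ACCi and vehicle livers. With the L code as a term, the 9 clock genes called at 5 mpk kept their direction. Their median log2 change was 2.04, against 2.31 without the term, while the median SE rose from 0.31 to 0.66 and 2 were still called. Vehicle and 5 mpk livers share no code, so this fit links them only through 1 mpk livers and 2 vehicle livers in L2. It therefore cannot settle how much the code contributes. Within L2 the mean clock score was 1.33 higher in 6 livers at 1 mpk than in the 2 with vehicle. Order of collection, read from the number in the animal's name, had a mean within-group rho of -0.05 with the clock score (permutation p = 0.774), and the clock score differed by 0.3 between the doses (permutation p = 0.284); the first decides nothing because the labels do not say that the numbers follow time, the second because the doses overlap. With the clock score as a term 48.9% of the other genes called at 5 mpk kept their call (1104 of 2256) and 2082 kept their direction, but the score is tied to the groups, so a clock shift as a cause of the rest and an effect of ACCi on the clock cannot be told apart. Both the hour of collection and a change of feeding by the drug may contribute, and the labels give neither.

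Some stellate cell wells with 1 inhibitor alone lay on the other inhibitor's side of a response score. On a score of the TGFb+ACCi response built from the other donors (357 to 550 genes), 4 of the 12 wells lay beyond both wells of the other inhibitor; they were all the scored wells of 1 donor, and the other 2 donors had none. An exchange of ACCi and TGFi labels may explain them, but the score orders wells by a response and cannot identify a treatment. The rule flags all 4 wells of a donor at once where both TGFi wells score above both ACCi wells, so they count as 1 event. In 3 of 3 donors both TGFb+ACCi wells lay above both TGFb wells, which argues against a donor without a response to ACCi in the presence of TGFb. The wells out of place had no added TGFb, so a donor without a response to ACCi alone cannot be judged this way. No biological explanation was tested beyond that.

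Of 38 livers, 8 stood apart from their group. A trend with GC content (an absolute rho over 0.5) was found in 4 of these 8 and in 0 of the other 30 (Fisher's exact p = 0.000948, two-sided), so GC bias in the library may account for part of them. The limit of 0.5 was set after the data were seen, and the highest of the other livers reached 0.47. Among the 4, chow replicates 7 and 8 were the only chow livers with code L5. The only 5 mpk liver with code L4, replicate 10, was another of them. In 1 mpk replicate 3, muscle genes at 127 CPM against at most 0.248 CPM in the other 37 livers make adherent muscle a candidate source. A chow liver labelled 1 mpk replicate 1 is argued against: Scd1 was at 2036 CPM (chow 133 to 792) and Sqle at 16.5 CPM (chow 43.5 to 158). Its Mup7 (4110 CPM) and Hsd3b5 (87.6 CPM, others 0.61 to 13.1) stay unexplained.

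Livers were split into groups of the same sizes, 40 splits per comparison with the real one. Only the real split gave as many genes. That share, 1 of 40 each, is the lowest that 40 splits can give. It argues against a random assignment of livers as the source of these counts, but cannot separate treatment from the L code. The counts were 6649 for diet against at most about 700 in the others, 456 at 1 mpk against 26, and 2265 at 5 mpk against 1. Between the doses the margin was smaller, 95 against 47. The smaller counts between the doses in other settings, such as 20 with only the 2 groups compared and 24 without the libraries marked T, were not put to splits. For stellate cells the splits are too few for a share under 0.05. TGFb gave 2713 genes against at most 3 in the other splits, TGFb+ACCi 178 against 4, and TGFb+TGFi 2940 against 0, each with 1 of 10 splits as large; ACCi alone, TGFi alone, and TGFb+TGFi against DMSO gave 0 in edgeR against 0 (10 of 10 as large; 801, 317 and 134 genes had an unadjusted p below 0.05, and DESeq2 called 3, 2 and 0). The interaction with TGFi gave 854 against 0 (1 of 4), and that with ACCi 0 in edgeR against 0 (4 of 4; 747 with an unadjusted p below 0.05, DESeq2 3).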

How the results depend on the processing

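Limma-trend, the clock score, leaving out the livers standing apart, each liver or the 4 wells out of place, and every test of TGFb+TGFi against DMSO were chosen after the data were seen; the other tests in this part were planned. RLE size factors and no low-count filter left every count of called genes within 1.5 times its value, and no scaling moved the median log2 fold change of all genes beyond 0.04. Of 2912 named-gene values in liver under these alternatives, 2517 kept direction and side of the threshold, 280 lost the call, 81 gained it, 27 moved and 7 reversed; of 5254 in stellate cells, 4316 kept both, 547 lost it, 345 gained it and 46 moved. Where a count below differs from its value in the report, the cause was not tested unless stated.

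In liver, the L code as a term gave 2230 genes for diet, 2172 of them shared, 2 at 1 mpk (1 shared) and 80 at 5 mpk (78 shared). Orm2 reversed for diet from a log2 fold change of 2.33 to -0.05. Vehicle livers share no code with chow or 5 mpk livers, so the term widens the errors, and a code effect can barely be told from a group effect. Estimates moved both ways: at 5 mpk Pitx3 went from -3.71 to -1.9 and Col1a1 from -1.16 to -1.88. DESeq2 gave 174 genes between the doses and limma-trend on unrounded values 58. With only the 2 groups compared, 853 were called at 1 mpk (430 shared) and 20 between the doses (18 shared). Without the libraries marked T, 24 were called between the doses. Without the 8 livers standing apart, 1800 were called at 1 mpk (449 shared), 3928 at 5 mpk (2113 shared) and 344 between the doses (75 shared). Leaving out livers for their distance from the group narrows the spread by construction, so these rises are partly built in.

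With the clock score as a term, 2395 genes were called at 1 mpk (176 shared), 4283 at 5 mpk (1108 shared) and 176 between the doses (83 shared). Some log2 fold changes reversed: for diet Cpt1a went from -0.28 to 1.21; at 1 mpk Cpt1a from 0.15 to -0.82, Dbp from 2.13 to -0.02 and Lipe from 0.75 to -0.12; at 5 mpk Dgat2 from 0.52 to -0.16 and Por from 1.25 to -0.06. Dbp is part of the score, so its reversal follows from how the score is made. Cpt1a at 5 mpk kept its direction and gained a call, going from -0.19 to -1.32 (adjusted p = 4.27e-04).

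Leaving out each liver in turn gave 6200 to 6924 genes for diet, 332 to 589 at 1 mpk, 1918 to 2678 at 5 mpk and 39 to 189 between the doses. Between the doses the count moved by over 1.5 times without 1 mpk replicate 9 (39), 10 (51), 2 (57), 6 (58) or 1 (189), and without 5 mpk replicate 5 (41), 6 (55), 8 (56), 3 (57), 4 (61), 2 (168) or 1 (180). Calls of named genes between the doses were lost without any 1 of 27 livers for Pygm (adjusted p up to 0.224, without 1 mpk replicate 3), 25 for Fhl1 (up to 0.132, 1 mpk replicate 10), 17 for Gpam (up to 0.0922, 5 mpk replicate 9), 9 for Gdf15 (up to 0.141, 1 mpk replicate 10), 8 for Saa1 (up to 0.08, 5 mpk replicate 5) and 5 for Myh11 (up to 0.0885, 1 mpk replicate 3). Pygm at 1 mpk lost its call only without 1 mpk replicate 3 (adjusted p = 0.0863). At 1 mpk Pitx3 was lost without any 1 of 11 livers (adjusted p up to 0.112, vehicle replicate 6), Timp1 without any 1 of 10 (up to 0.0798, vehicle replicate 7) and Cyp26b1 without vehicle replicate 4 (adjusted p = 0.0508); at 5 mpk Timp1 was lost without vehicle replicate 7 (adjusted p = 0.0522).

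In stellate cells, 36 unsummed wells with a donor term gave 5284 genes for TGFb, 274 for ACCi, 33 for TGFi, 3537 for TGFb+ACCi, 5475 for TGFb+TGFi, about 1.1e2 (rounded) for the ACCi interaction and 3373 for the TGFi interaction. A replicate block of donor by replicate number gave 4998, 123, 19, 3237, 5206, 30 and 3094 in that order. Both treat wells of 1 donor as independent, which raises the counts by construction. DESeq2 on donor sums gave 3 for ACCi, 2 for TGFi, 1022 for TGFb+ACCi, 3 for the ACCi interaction and 1401 for the TGFi interaction. In the simulation of TGFb+ACCi against TGFb, 15.9% of DESeq2 calls were unchanged genes, against 3.5% of edgeR calls. Without the donor term 330 were called for TGFb, 0 for TGFb+ACCi (1121 with an unadjusted p below 0.05 in edgeR), 416 for TGFb+TGFi and 4 for the TGFi interaction, since differences between donors then enter the error. With only the 2 treatments in the fit 1373 were called for TGFb, 1 for ACCi, 2107 for TGFb+ACCi, 1448 for TGFb+TGFi and 17 for TGFb+TGFi against DMSO. Without the 4 wells out of place, 33 were called for ACCi and 1152 for TGFb+ACCi, which kept all 178. The rise for ACCi is partly built in, since its wells left out were those scoring low for the ACCi response. For TGFb+ACCi none of its own wells was left out, so its rise came through the shared fit and is no independent evidence.

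Leaving out each donor in turn gave 828 to 1762 genes for TGFb, 0 to 4 for ACCi, 0 to 0 for TGFi, 0 to 52 for TGFb+ACCi, about 7.1e2 (rounded) to 2112 for TGFb+TGFi, 0 to 0 for the ACCi interaction and 43 to 349 for the TGFi interaction; fewer donors leave fewer degrees of freedom.

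With the correlation estimated per list, the lists that passed fell from 17 to 0 for diet, 10 to 2 at 1 mpk, 13 to 0 at 5 mpk, 10 to 1 between the doses, 11 to 3 for TGFb, 13 to 1 for ACCi, 10 to 3 for TGFi, 13 to 2 for TGFb+ACCi, 9 to 2 for TGFb+TGFi, 6 to 0 for the ACCi interaction, 13 to 2 for the TGFi interaction and 1 to 0 for TGFb+TGFi against DMSO. With the vehicle livers split between the comparisons, 118 genes at 1 mpk and 678 at 5 mpk were opposite to the diet, against 399 and 1857; each comparison then has fewer vehicle livers.

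No test here varied depth. On simulated data edgeR recovered 69.7% of 1.5-fold changes in the liver design and 14.9% in the stellate cell design.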

Other observations

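The test in this part, of a response to ACCi shared by livers and stellate cells, was written down before its result was seen, and no test in it was chosen afterwards.

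A shared response would put genes called in livers at 5 mpk and in TGFb-treated stellate cells with ACCi in the same direction more often than not. Of 9249 symbols tested in both species, 1570 were called in liver and 121 in stellate cells. Both called 35, where 20.5 would be expected for independent lists, and 20 of the 35 had the same direction, 7 higher and 13 lower (binomial exact p = 0.5). Whatever their p in liver, 62 of the 121 had the same direction. Both shares lie near an even split, so no broadly shared direction was seen. A response shared by fewer genes stays open as a hypothesis, since the overlap of 35 is too small to decide. COL1A1 was lower in both (log2 fold change -1.16 in liver and -0.77 in stellate cells), as were THBS1 (-0.92 and -1.93) and FBLN5 (-0.77 and -1.17), while ELOVL6 was higher in both (1.75 and 0.56). ATF3 went apart (-0.82 and 2.82), as did LPIN1 (-1.15 and 1.26).

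The correlation of log2 fold changes across genes between diet and 5 mpk was -0.66, and -0.49 with the vehicle livers split between the comparisons; in simulations of unchanged groups that share their vehicle livers it was -0.458. Between diet and 1 mpk it was -0.59, -0.37 with the livers split, and -0.461 in simulations. Between TGFb and TGFb+TGFi it was -0.95, -0.87 with the wells split, and -0.489 in simulations. Between TGFb and TGFb+ACCi it was -0.34, -0.28 with the wells split, and -0.491 in simulations. The covariances were -0.129 for diet and 1 mpk (simulated -0.014, split -0.088) and -0.193 for diet and 5 mpk (simulated -0.014, split -0.155). For TGFb and TGFb+ACCi the covariance was -0.186 (simulated -0.06, split -0.172), and for TGFb and TGFb+TGFi -0.756 (simulated -0.061, split -0.766). The split vehicle livers keep the same codes and the split wells the same donors, so a split does not make the comparisons independent. Genes are not independent replicates, so these values carry no test.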
